A study of Mus musculus with 8 samples.

How the data were processed

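RNA-seq was done on 8 libraries of C57BL/6 mouse bone marrow, with 1 library in each of 8 groups. Per the labels, 4 libraries came from GFP-positive leukaemia cells sorted by surface antigens and 4 from normal cells sorted with the matching antigens. Per the labels' protocols, RNA was extracted with Trizol, poly(A) RNA was captured with oligo(dT), cDNA was random-primed, and paired-end sequencing was done on an Illumina HiSeq instrument. Per the submitters' processing notes, reads with adaptors or uncertain bases were removed, the genome build was mm10, and STAR, HTSeq and edgeR were used. No versions or settings of these tools were stated.

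The deposited table holds FPKM (fragments scaled by gene length and library total) made by the authors, for 16434 genes in the 8 libraries. Its name refers to differential genes and the rule by which genes entered it is not stated. Of 12646 genes with FPKM of at least 1 in some library, 96.6% differed at least 2-fold between some 2 libraries, so genes that varied little are probably under-represented and shares of genes refer to the listed genes only. It holds 11609 genes that GENCODE vM21 calls protein-coding, of 22028 in that annotation. Gene lengths were the mean transcript lengths of GENCODE vM21, available for 16380 genes. Deposited FPKM multiplied by length fell on whole multiples of 1 step per library, within 0.02 of a fragment, for 94.1% to 94.6% of tested values of single-transcript genes. Over all tested values, including genes with several transcripts, the share was 67.2% to 70.1%. That step gives the total number of fragments per library and an estimate of the fragments behind each value, rounded to whole fragments. For values off the whole multiples this estimate is approximate. For a gene of median length (1562 bases), an FPKM of 1 in the B-ALL library rests on 67.0 fragments, and its 95% Poisson interval is 0.775 to 1.27. An FPKM of 10 has the interval 9.26 to 10.8 in the same library.

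Values were compared as log2(FPKM + 1) with the deposited scaling. A log2 ratio is leukaemia minus normal on that scale, whereas a fold is the ratio of the FPKM values themselves. Each leukaemia was compared with the normal cells of the same gate. With 1 library per group these comparisons have no replicate check and no p-value. Genes were counted as different when the absolute log2 ratio was at least 1 and FPKM was at least 1 in the higher library. Fold intervals are 95% intervals for the ratio of 2 counts, and a fold against 0 fragments is a lower bound that uses 3 fragments as the floor of that library. Both cover counting error only.

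There were 32 gene lists, for the MYC network, growth and cell cycle, blood lineages, interferon, antigen presentation, cell death and other functions. Each list's median log2 ratio was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and called higher or lower when it lay outside their central 95%. This describes the libraries and is no test between conditions. Overlaps of called genes were set against the number that independent calls would give. Lineage differences were compared by Pearson correlation across genes, which are not independent replicates.

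Across lineages, limma (lmFit, eBayes with a trend) was fitted to the 11071 genes with FPKM of at least 1 in at least 2 libraries, with the gate as a block of 4 levels, which leaves 3 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The pairing comes from the gate, not from an animal or replicate number. As a check of it, the genes by which each leukaemia differed from the other leukaemias were correlated with those by which its paired normal library differed from the other normal libraries. The correlations were 0.37 for B, 0.41 for T, 0.36 for myeloid and -0.23 for lineage-negative cells. Lists were tested with camera (preset correlation 0.01, two-sided) in the same fit, and again with the correlation estimated from the data and with fry, which tests whether a list's genes move on balance in one direction. Mycn and Myc were also tested with an exact two-sided sign-flip permutation over the 4 pairs.

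Named genes were taken by rule: Mycn and Myc, the 10 highest and 10 lowest log2 ratios per comparison among genes with FPKM of at least 10 in the higher library, and up to 4 members of each described list with FPKM of at least 5. Across lineages the rule took the 10 highest and 10 lowest mean log2 differences that passed limma in the same direction in 4 of 4 pairs, and between leukaemias the 5 genes highest over the next leukaemia with FPKM of at least 20. Receptor segments (438) and predicted or clone-named genes (4169) were left out of naming within the single comparisons and only counted, and any other gene of a fixed list could be named to give its value. Not every gene that the rule took is named in the text. The groups, lists, tests, rules and most alternatives were fixed before the data were examined.

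Alternatives were pseudocounts of 0.1 and 5, scaling by median ratios over 6229 genes with FPKM of at least 1 in every library, scaling to a common FPKM sum per library, quantile normalization, no FPKM filter or a minimum of 5, a 4-fold rule, no block, each pair left out, no trend, removal of receptor segments with the 50 highest genes left out of scaling, and unmatched random lists. Limma-voom on recovered fragments, and counts without genes at least 4-fold higher in another normal population, were added after the data were seen. The median-ratio size factor was 0.585 for the normal myeloid library and 0.962 to 1.18 for the others. Limma was tested on simulated data with 11045 genes: at a dispersion of 0.1 it recovered 7.5% of 2-fold and 99.0% of 4-fold changes, and at a dispersion of 0.4 it recovered 64.5% of 8-fold changes and none of 4-fold. The software was Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. Isoforms, splicing, sequence variants and genes outside the table were not analysed here.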

Results

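Poly(A) RNA was sequenced from 4 leukaemias that arose in mice with N-Myc overexpression and from 4 normal bone marrow populations. The leukaemias were B-cell acute lymphoblastic leukaemia (B-ALL, sorted as B220+ GFP+), T-cell acute lymphoblastic leukaemia (T-ALL, CD3+ GFP+), acute myeloid leukaemia (AML, Mac1+ Gr1+ GFP+) and acute undifferentiated leukaemia (AUL, negative for B220, CD3, Mac1 and Gr1, GFP+). Their normal counterparts were B220+ B cells, CD3+ T cells, Mac1+ Gr1+ myeloid cells and lineage-negative cells. Each group had 1 library, so comparisons within a lineage have no replicate check and no p-value. Totals recovered from the steps of the table's values were 42874116 fragments for B-ALL, 43206624 for T-ALL, 42308253 for AML and 33818615 for AUL. The normal B, T, myeloid and lineage-negative libraries had 39886613, 37000630, 52280283 and 44474272. The listed genes held 70.8% to 80.1% of these fragments.

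All 4 leukaemias had high levels of Mycn transcripts, and the values cannot separate introduced from endogenous transcripts. Mycn, which encodes the transcription factor N-Myc (ENSMUSG00000037169, mm10 chromosome 12, 12936096 to 12941914), had an FPKM of 1587 in B-ALL, 843 in T-ALL, 1858 in AML and 719 in AUL. In the matched normal cells it had 1.66, 0.594, 0.518 and 5.24. The folds were 953 in B-ALL (95% counting interval 803 to 1141), 1421 in T-ALL (1055 to 1964), 3589 in AML (2745 to 4794) and 137 in AUL (125 to 151). Myc, its paralogue c-Myc (ENSMUSG00000022346, chromosome 15, 61985391 to 61990374), went the other way in all 4 leukaemias. It had 2.35, 0.874, 0.251 and 0.907 in the leukaemias against 47.4, 98.2, 6.45 and 89.95 in the normal cells, which is 20.1-fold, 112-fold, 25.7-fold and 99.2-fold lower. Over the pairs the mean log2 difference was 8.84 ± 1.43 (SD, n = 4) for Mycn and -4.43 ± 1.502 (SD, n = 4) for Myc. The exact two-sided sign-flip permutation p was 0.13 for both genes, the smallest that 4 pairs can give. Mycl, the third family member, had 0.0816 in B-ALL against 30.0 in normal B cells.

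**Figure D1:**
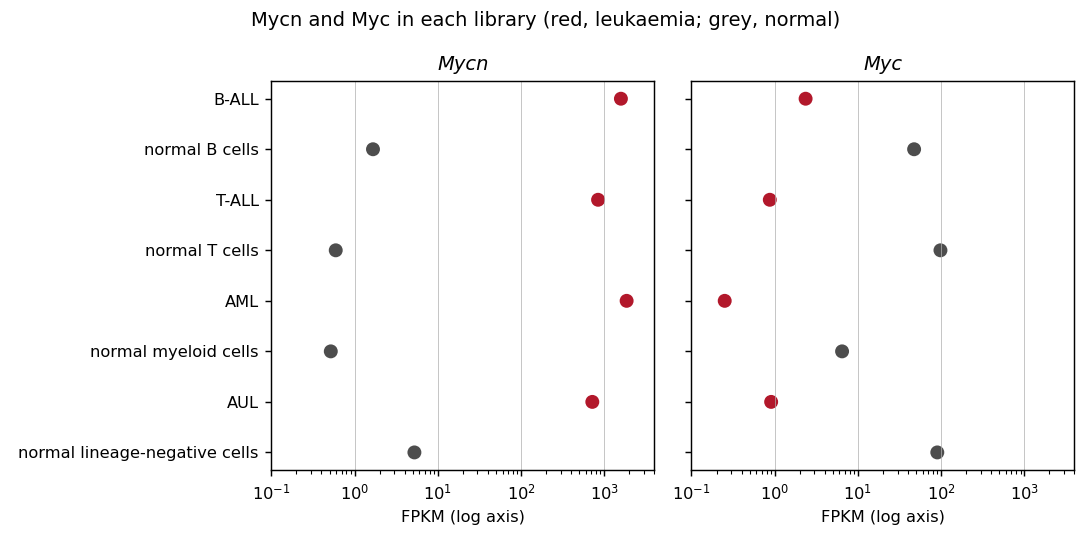
FPKM (log axis) of Mycn and Myc in the 4 leukaemia libraries (red) and the 4 normal libraries (grey), 1 point per library. Mycn lies between 719 and 1858 in the leukaemias and at 5.24 or less in the normal libraries, while Myc is lower in each leukaemia than in its normal counterpart.

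B-ALL cells were set against normal B220+ cells to ask how the leukaemia differs from the normal cells of its gate. Ribosome biogenesis and metabolic genes were higher and genes of mature B cells lower in B-ALL. All 28 nucleolar ribosome biogenesis genes were measured and 26 of them were at least 2-fold higher, with a list median log2 ratio of 1.96. Among them were Gnl3 (nucleostemin; 170.3 against 30.2 FPKM, log2 ratio 2.46) and Ppan (254.7 against 47.3, 2.40). Of 26 metabolic genes, 24 were at least 2-fold higher (median 2.08), such as Srm, the spermidine synthase (492.1 against 46.2, 3.38), and Ldha, lactate dehydrogenase (1654 against 263.3, 2.65). DNA replication genes were higher too (21 of 27, median 1.29), including Cdc45 (1.71), whereas mitotic genes had a median of 0.72 with 9 of 27 at least 2-fold higher.

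Single genes moved further. Cdkn2a (chromosome 4, 89274471 to 89294653), which encodes a cell-cycle inhibitor and an activator of p53, had 219.9 FPKM in B-ALL and 0.430 in normal B cells, 511-fold higher (309.5 to 913). Foxf2, a forkhead transcription factor, had 60.1 and was not detected in normal B cells, at least 1887-fold higher. The protease inhibitor Serpine2 (74.8 against 1.28), the laminin chain Lamb2 (51.4 against 0.914) and the glycoprotein Fstl1 (57.4 against 1.30) were also among the highest. Ankrd13b (80.2 against 1.44), Camkv (52.7 against 1.56) and the carbonic anhydrase Car12 (30.04 against 0.354) completed the non-receptor genes at the top, beside Cd3e of the T-cell receptor complex (23.8 against 0.244). At the other end stood the IgE receptor Fcer2a (0.634 against 299.6, log2 ratio -7.52), the IgM receptor Fcmr (4.24 against 578, -6.79) and Siglech, a receptor of plasmacytoid dendritic cells (1.59 against 360.6, -7.12). The normal B library thus held RNA of plasmacytoid dendritic cells, and the fall of their genes can reflect those cells. Klk1, a kallikrein, rested on 2 fragments in B-ALL against an FPKM of 85.6 (1506-fold lower, 416 to 12437). Cd300c (-5.84), Cd4 (-5.82), the lectin Clec10a (-5.58), the ribonuclease Rnase6 (-5.48), Adam11 (-5.46) and Lynx1 (-5.33) were the others.

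The mature B, pro-B and pan-B lists were all lower in B-ALL. The 16 mature B and MHC class II genes were all at least 2-fold lower (median -3.004), such as complement receptor Cr2 (0.475 against 58.1). Of 12 pro-B and pre-B genes, 8 were at least 2-fold lower (median -2.78), including the surrogate light chain gene Igll1 (1.09 against 67.1) and Dntt, the terminal transferase (-4.74). The pan-B list had a smaller median of -1.15, with 7 of 13 genes lower, such as Spib (228.7 against 1176). Plasmacytoid dendritic cell genes (8 of 8, median -4.62), NK cell genes (8 of 8, -3.06), interferon response genes (14 of 19, -1.99), immediate early genes (17 of 21, -1.73) and MHC class I genes (7 of 11, -1.48) were lower as well. Among markers of other cells, monocyte (11 of 17, median -1.45), mast cell and basophil (5 of 6, -1.77), thymocyte (7 of 13, -1.39) and effector T genes (8 of 14, -1.33) were also lower than in the normal B library. That library held RNA of other cells, with Prss34 at 84.5 beside Siglech. Lower markers of other cells in B-ALL can therefore reflect the content of the normal library. The neutrophil and pan-T lists were higher. All 21 neutrophil genes were at least 2-fold higher (median 1.77), for example Lcn2 (620.9 against 120.4), and so were 14 of 19 pan-T genes (median 1.73), for example Cd3d (30.3 against 0.991) and Tcf7 (85.0 against 6.81). By the 2-fold rule 1929 genes were higher and 2319 lower of 10608, and 1569 and 2197 without genes at least 4-fold higher in another normal population.

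T-ALL cells were set against normal CD3+ T cells. T-ALL had the highest medians of the replication and mitosis lists among the 4 comparisons, and lower levels of mature T-cell genes. These medians also depend on the normal library. Mki67 had 160.4, 129.6, 80.8 and 128.9 in B-ALL, T-ALL, AML and AUL. In normal B, T, myeloid and lineage-negative cells it had 111.7, 34.5, 92.0 and 135.9. The medians therefore do not rank the leukaemias themselves. All 27 mitotic genes were at least 2-fold higher (median 2.24), such as cyclin B1 (Ccnb1, 90.6 against 9.45), Aurka (68.6 against 7.71) and Plk1 (log2 ratio 2.97), and all 27 replication genes were too (median 2.19), such as Mcm10 (61.4 against 4.91) and Cdc6 (2.97). Metabolic genes had a median of 1.91 (24 of 26), led by Psat1 of serine synthesis (314.7 against 35.6). Ribosome biogenesis genes had a median of 1.31 (22 of 28), with Polr1b of RNA polymerase I at 98.8 against 21.6 and Nop56 at 577.5 against 153.7. Of 17 effector T genes 14 were at least 2-fold lower (median -4.71), including the homing regulator Klf2 (4.57 against 463) and the granzyme gene Gzmb (log2 ratio -6.01), although another granzyme gene, Gzma, was higher (731.7 against 97.2).

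The chemokine gene Ccl5 had the lowest log2 ratio (0.926 against 1236, -9.33, 1335-fold lower). The CD8 co-receptor gene Cd8a was not detected in T-ALL (237.7 in normal T cells, at least 9190.4-fold lower), nor were the NK receptor genes Klrd1 (252.8, at least 2442-fold lower) and Klrk1 (133.5, at least 3343-fold lower). Cd8b1 (-7.82), the T and NK cell antigen gene Cd7 (-7.38), the chemokine genes Ccl4 (-6.89) and Xcl1 (1 fragment; 3129.5-fold lower, 561 to 123654), and the mast cell and basophil proteases Prss34 (-7.21) and Mcpt8 (-6.77) followed. Mpp4, a membrane scaffold protein of the guanylate kinase family, had the highest log2 ratio after Mycn among the genes that could be named (77.1 against 0.112, 6.13), with alkaline phosphatase (Alpl, 257 against 2.93, 6.04) and the p53 target Perp (106 against 1.86, 5.23). The transcription factor gene Batf3 rested on 3 fragments in normal T cells (346-fold higher, 118 to 1679) and the plastin gene Pls1 on 1 (1807-fold higher, 324 to 71403). Dnph1, a nucleotide hydrolase (5.11), Gcsam (4.97), the complement gene Hc (4.93) and Fibcd1 (4.82) were the others at the top.

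The pan-T genes themselves stayed within the range of random lists in T-ALL (median -0.29), with Cd2 lower (65.5 against 319.2) and Gata3 higher (114.8 against 51.5). Thymocyte and Notch target genes were lower (11 of 13, median -3.76), including Dtx1 (-4.93) and the IL-2 receptor gene Il2ra (-4.01). Interferon response genes (16 of 19, median -2.64), immediate early genes (16 of 21, -3.19; Fos 7.55 against 858.6) and MHC class I genes (9 of 11, -1.96; H2-K1 410.2 against 3812) were lower. The normal T library held RNA of other cells, with Pax5 at 149.5 and Prss34 at 293.7. Beside this, pan-B genes (13 of 13, median -4.87; Pax5 1.06 against 149.5), mature B and MHC class II genes (15 of 16, -3.51; Cd74 6.14 against 353.8), NK cell genes (8 of 8, -4.45) and mast cell and basophil genes (6 of 6, -4.70) were lower in T-ALL. With members at 0 fragments at their bound, the interferon, NK and mast cell medians in T-ALL were -2.91, -4.77 and -6.99. The 2-fold rule called 2309 genes higher and 2514 lower of 10461, with 47.9% of the calls higher. Median-ratio scaling gave 1631 and 3070 (34.7% higher) and moved the median gene from 0.03 to -0.25.

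AML cells were set against normal Mac1+ Gr1+ cells. AML had the highest medians of the ribosome biogenesis and metabolism lists among the 4 comparisons, and lower levels of genes of mature neutrophils. The normal library matters here too. Dkc1 had 363.5, 278.9, 358.3 and 302.3 in B-ALL, T-ALL, AML and AUL, and Npm1 had 2232, 2170, 1762 and 3045. In normal myeloid cells they had 11.8 and 84.9, against at least 83.2 and 437.9 in the other normal libraries. Ribosome biogenesis genes had a median log2 ratio of 3.94, with 27 of 28 at least 2-fold higher, such as dyskerin (Dkc1, 358.3 against 11.8) and Gnl3 (4.72). Metabolic genes had a median of 3.44 (23 of 26), led by Phgdh, the entry enzyme of serine synthesis (557 against 10.2, 54.7-fold), and Srm (463.4 against 11.4). All 17 ribosomal protein genes were at least 2-fold higher (median 2.51), as were 24 of 27 replication genes (median 1.88, Mcm2 2.53). These log2 ratios are under the deposited scaling and are lower under median-ratio scaling, which divides AML by 1.17 and normal myeloid cells by 0.585. The neutrophil genes were lower without exception (21 of 21, median -6.09), while 8 of 10 promyelocyte granule genes, which mark an earlier stage, were higher (median 2.24), such as cathepsin G (Ctsg, 1127 against 72.3), neutrophil elastase (Elane, 3481 against 445.5) and myeloperoxidase (Mpo, 2220.1 against 354.4).

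The gelatinase Mmp9 had the lowest log2 ratio of AML (1.37 against 3723, -10.62, 2719.6-fold lower). Retnlg (9.37 against 7482, -9.50), the collagenase Mmp8 (1.42 against 1130.3, -8.87), lactoferrin (Ltf, 66.4 against 26716, -8.63) and the formyl peptide receptor Fpr2 (-8.06) belonged to the same mature stage. The cytokine gene Il1b (-8.97), the antiviral genes Ifitm6 (-8.88) and Ifitm3 (-8.60), the phospholipase-like Plbd1 (-8.82) and the inhibitory receptor Lilrb4a (-8.54) were also among the lowest. Ngp (3881 against 23489) and Camp (1822 against 10386) stayed abundant, while the chemokine receptor Cxcr2 (0.287 against 329) and the integrin Itgam, which is the Mac1 antigen of the gate (1.63 against 208), were low in AML. Dmrt1, a transcription factor of germ cells, had 90.8 and was not detected in normal myeloid cells (at least 2549-fold higher). Cyp26a1, which degrades retinoic acid (78.9 against 0.119), the folate carrier Slc19a1 (143 against 1.63), the matrix protein Thbs4 (59.9 against 0.148), glypican-3 (Gpc3, 55.6 against 0.0841), the fetal RNA-binding protein Igf2bp3 (50.6 against 0.121) and Clstn3 (100.8 against 1.27) were also among the highest.

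Monocyte genes (16 of 18, median -3.68; Csf1r 0.276 against 56.1), interferon response genes (17 of 19, -3.79; Irf7 1.30 against 95.5), adhesion genes (7 of 11, -2.94) and mature B and MHC class II genes (7 of 8, -3.37, or -4.73 with members at 0 fragments at their bound) were lower in AML. Mitotic genes had a median of 0.68, within the range of random lists, and it flipped to -0.25 under median-ratio scaling. Of 19 pan-T genes, 12 were at least 2-fold higher in AML at low levels (Thy1 38.3 against 3.67), but their median of 1.27 lay within the range of random lists. AML also had the alpha segment Trav21-dv12, at 11.2 against 453.3 in AUL, beside Cd3d at 7.60 against 275.8 and Lck at 14.4 against 626 in AUL. A few genes filled the normal myeloid library: S100a8 and S100a9 took 7.02% of its fragments and its top 10 genes 18.7%, against 5.67% to 6.88% in the other libraries. The 2-fold rule called 4311 genes higher and 2662 lower of 9965 (61.8% higher), and the median gene was at 0.56. Median-ratio scaling gave 2477 higher and 4410 lower (36.0% higher) with the median gene at -0.48, so the balance of higher and lower genes in AML turned with the scaling. Scaling to a common FPKM sum placed it at 0.77. Without genes at least 4-fold higher in another normal population, 3012 were higher and 2346 lower.

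AUL cells were set against normal lineage-negative cells. That library was a mixture: beside stem and progenitor genes it held RNA of committed cells, such as Igha at 672 and the basophil gene Prss34 at 1436. AUL had higher levels of T-cell genes and lower levels of stem and progenitor genes. Of 19 pan-T genes 18 were at least 2-fold higher (median log2 ratio 4.05), including the CD3 chains Cd3d (275.8 against 6.77), Cd3e (57.4 against 1.06) and Cd3g (183 against 3.84), the kinase Lck (626 against 26.03) and the transcription factor Tcf7 (523 against 9.74), although the gate excluded CD3+ cells. Of 22 stem and progenitor genes 18 were at least 2-fold lower (median -3.11, or -4.34 with members at 0 fragments at their bound), including Gata2 (0.473 against 141.2), Cd34 (0.148 against 68.8) and Kit (0.549 against 57.9). Gata2 had 9.49, 51.8, 10.8 and 141.2 in normal B, T, myeloid and lineage-negative cells, and Prss34 had 84.5, 293.7, 99.4 and 1436. The fall of Gata2 thus cannot be told apart from a loss of basophil RNA. Ribosome biogenesis genes (16 of 28, median 1.10, Npm1 3045 against 757.3) and metabolic genes (16 of 26, 1.15, Ldha 2189 against 596.6) were higher. Replication genes (0.33) and mitotic genes (0.28) lay within the range of random lists. This does not mean low levels in AUL. Mcm6 had 321.1 in AUL, against 205.5 to 277.8 in the other leukaemias. It had 211.6 in lineage-negative cells, against 39.6 to 83.2 in the other normal libraries.

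Pdcd1, the inhibitory receptor PD-1 of activated T cells, was highest in AUL (289 against 0.221, 7.89, 1305-fold, 835 to 2168). The granzyme gene Gzmk (107 against 0.105, 6.61), Trat1 of the T-cell receptor complex (73.7 against 0.230, 5.92), the integrin Itgad (92.4 against 1.05, 5.51) and Kctd15 (73.9 against 0.231, 5.93) followed. The receptor kinase gene Ret (85.6 against 0.632, 5.73) and the channel gene Trpm1 (1 fragment in normal cells; 4409-fold higher, 791 to 174216) were also in this group. The transcription factor Eomes of effector cells was higher (86.7 against 6.70), and so was Tox (20.1 against 1.17). Mcpt8 (0.726 against 819, -8.89), Prss34 (2.80 against 1436, -8.56) and Cpa3 (0.480 against 155, -6.72), proteases of mast cells and basophils, were lowest together with the chemokines Ccl3 (-7.76) and Ccl4 (-6.73). Myeloperoxidase (Mpo, 33.6 against 4089, -6.88), cathepsin G (Ctsg, -6.76), and the B-cell factors Spib (-7.12), Vpreb3 (-6.90) and Pax5 (0.530 against 164, -6.75) were lower as well.

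The lineage-negative library held RNA of committed B-lineage cells, with Pax5 at 164, and of neutrophils, with Ltf at 2785 and Ngp at 2436 against 26716 and 23489 in normal myeloid cells. Beside this, 12 of 13 pan-B genes (median -6.12), 11 of 12 pro-B and pre-B genes (-4.53), 8 of 10 promyelocyte genes (-5.22), 21 of 21 neutrophil genes (-3.11), 18 of 18 monocyte genes (-2.91), 7 of 7 mast cell and basophil genes (-6.45) and 8 of 8 NK cell genes (-3.68) were at least 2-fold lower in AUL. With members at 0 fragments at their bound, the pro-B, monocyte and NK medians were -5.48, -2.95 and -4.23. Interferon response genes (19 of 20, median -1.90) and immediate early genes (15 of 21, -1.87; Jun -5.02) were lower too, while Egr3 was higher (3.52). The 2-fold rule called 1461 genes higher and 3179 lower of 10759, with a median gene at -0.18. Scaling to a common FPKM sum moved the median gene to -0.29, and leaving out genes at least 4-fold higher in another normal population gave 1193 and 2749.

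**Figure D2:**
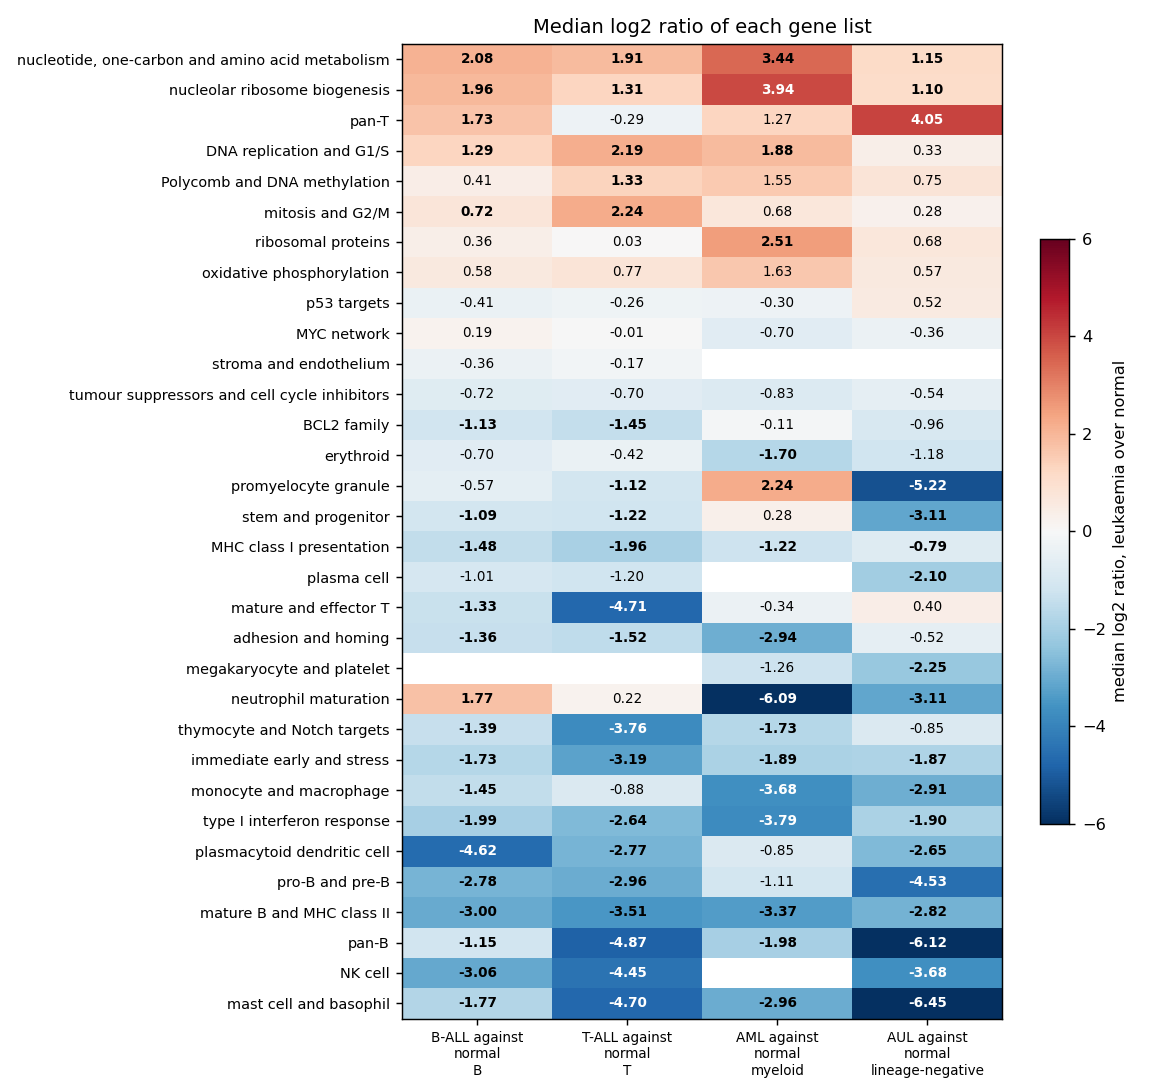
Median log2 ratio (leukaemia minus normal, colour scale from -6 to 6) of the gene lists in the 4 comparisons, with bold values outside the central 95% of random lists of matched expression. Metabolic and ribosome biogenesis lists are higher in all 4 leukaemias, and the interferon response list is lower in all 4.

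Changes shared by the 4 lineages were tested with limma with the gate as a block (n = 4 pairs). Beside Mycn (8.84 ± 0.54 SE, adjusted p = 0.00338), the genes that rose most were Rpph1, the RNA of ribonuclease P (chromosome 14, 50807449 to 50807767; 4.44 ± 0.32, adjusted p = 0.00527), Pdcd1 (4.39 ± 0.85, 0.0428), the centromere protein Cenpv (4.14 ± 0.33, 0.00727) and Alpl (3.79 ± 0.69, 0.0418). The T-cell receptor constant segment Tcrg-C2 (3.77), Nlgn2 (3.76), the branched-chain aminotransferase Bcat1 (3.48), Ankrd13b (3.40) and the long non-coding RNA Crnde (3.39) completed the 10 highest. Pdcd1, Alpl, Tcrg-C2 and Bcat1 were low in AML, at 4.57, 2.45, 5.74 and 2.47 FPKM, against 289, 133, 79.0 and 68.0 in AUL. AML also had the AUL segment Trav21-dv12 at 11.2 against 453.3, and RNA of AUL cells as a source of these AML values was not tested. In B-ALL, Tcrg-C2 stood at 10.1% of T-ALL, near the median of the pan-T list (9.63%), beside the T-ALL segment Trdv1 at 58.9. Pdcd1 (25.1%), Alpl (93.3%) and Bcat1 (174%) stood above that median. Other T-lineage cells stay open as a source of the Tcrg-C2 value in B-ALL. The genes that fell most were Prss34 (-6.22 ± 0.86, adjusted p = 0.0326), the chemokines Ccl5 (-5.40 ± 0.93, 0.0418), Ccl4 (-5.22) and Ccl3 (-4.78), the lipid hydroxylase Cyp4f18 (-4.94), the signalling regulator Rgs1 (-4.79), Ly6d (-4.77), Spib (-4.74) and the immunoglobulin segments Igkv6-23 (-4.83) and Igkj3 (-4.77). Myc fell as well (-4.43 ± 0.62, 0.0326). Among the genes that fell most, Prss34 had 84.5, 293.7, 99.4 and 1436 FPKM in normal B, T, myeloid and lineage-negative cells. The B-cell factor Spib had 152.1 in normal T cells. Falls of such marker genes can reflect other cells in the normal libraries, which was not tested. In all, 140 genes rose and 268 fell of 11071, each in 4 of 4 pairs, and none passed without the myeloid pair (smallest adjusted p 0.0554).

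Each pair mattered for this count, and so did the block and the treatment of low values: limma called 8 higher and 33 lower without the block, and 3 and 0 with a pseudocount of 5 or without the FPKM filter (3683 and 4366 at an unadjusted p under 0.05). In 4 of 4 pairs, 2863 genes were higher (25.9%) and 2697 lower (24.4%), where chance gives 6.25% in each direction, and 3920 genes had an unadjusted p under 0.05. Leaving out the B pair gave 11 higher and 158 lower, the T pair 2 and 1, the myeloid pair 0 and 0 (limma, 3566 at an unadjusted p under 0.05), and the lineage-negative pair 2 and 1. Quantile normalization raised the share of higher calls from 34.3% to 56.6% (659 higher, 506 lower), and median-ratio scaling moved the median gene from -0.08 to -0.31.

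By camera with the preset correlation, 7 lists were higher across the lineages, and none of them passed with an estimated correlation or by fry. All 28 ribosome biogenesis genes were tested, with a median difference of 2.07: 6 rose over all genes, including nucleophosmin (Npm1, 2.63 ± 0.53 SE), Polr1b (2.52 ± 0.47) and nucleolin (Ncl, 2.35 ± 0.50), and 27 rose adjusted over the list alone. The camera adjusted p was 2.63e-12, and the adjusted p = 0.332 with an estimated correlation. Of 26 metabolic genes (median 2.14) 12 rose over all genes, including Srm (3.05 ± 0.63), the amino acid transporter Slc7a5 (2.63 ± 0.48), the pyrimidine enzyme Cad (2.62 ± 0.44) and the serine hydroxymethyltransferase Shmt2 (2.43 ± 0.45), and 23 rose adjusted over the list alone (camera adjusted p = 7.50e-12; adjusted p = 0.332 with an estimated correlation). DNA replication genes had a median of 1.35, with 0 of 27 passing over all genes and 21 adjusted over the list alone (limma; camera adjusted p = 2.70e-09; adjusted p = 0.334 with an estimated correlation). Mitotic genes had a median of 0.99 with none passing either way (limma; camera adjusted p = 2.25e-06; adjusted p = 0.447 with an estimated correlation). Pan-T genes had a median of 1.71, where Tcf7 rose (3.30 ± 0.67) and 3 rose adjusted over the list alone (camera adjusted p = 5.89e-05; adjusted p = 0.409 with an estimated correlation). The pan-T medians of the single comparisons were 1.73 in B-ALL (beside the Trbv2 segment at 41.3), -0.29 in T-ALL, 1.27 in AML and 4.05 in AUL. Those of T-ALL and AML lay within the range of random lists. In B-ALL, Tcf7 stood at 9.63% of T-ALL, the median ratio of the pan-T list. Other T-lineage cells stay open as a source of these B-ALL values. Oxidative phosphorylation genes (0.93; camera adjusted p = 0.000145; adjusted p = 0.332 with an estimated correlation) and ribosomal protein genes (0.91; 0.00266; adjusted p = 0.571 with an estimated correlation) also moved up as lists, with no single member passing over all genes or adjusted over the list alone. Of 32 oxidative phosphorylation genes only 16 were measured, and their median lay within the range of random lists in all 4 comparisons. The median of the ribosomal protein list was highest in AML (2.51), the only comparison where it lay outside that range. In T-ALL the ribosomal protein median flipped from 0.03 to -0.27 under median-ratio scaling. No single-gene call of these lists held without the myeloid pair, where the smallest limma adjusted p over all genes was 0.0554. Without the T pair limma called only 3 of all genes, and without the lineage-negative pair also 3.

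Interferon response, immediate early, MHC and monocyte lists were lower by camera with the preset correlation, and none of them passed by fry. The 20 interferon response genes had a median of -2.28: 8 fell over all genes, including Irf7 (-3.63 ± 0.54 SE), Usp18 (-3.38 ± 0.46) and Isg15 (-3.34 ± 0.61), and 18 adjusted over the list alone (camera adjusted p = 9.40e-10). Of 21 immediate early genes (median -2.27) 10 fell, including Jun (-3.77 ± 0.80), Fos (-3.69 ± 0.70) and the RNA-destabilising Zfp36 (-3.23 ± 0.41), and 14 adjusted over the list alone (1.08e-06). Of 16 mature B and MHC class II genes (-2.81) 6 fell, such as H2-Aa (-4.54 ± 0.58) and the invariant chain Cd74 (-4.37 ± 0.59), and 15 adjusted over the list alone (4.00e-08). Of 11 MHC class I genes (-1.37) 3 fell, such as H2-T23 (-2.73 ± 0.51), and 8 adjusted over the list alone (0.000136). Of 18 monocyte genes (-2.06) 5 fell, such as Klf4 (-4.00 ± 0.41) and the cathepsin Ctss (-3.90 ± 0.66), and 14 adjusted over the list alone (5.16e-07). For these 5 lists the adjusted p = 0.332 with an estimated correlation. Here too no single gene passed limma without the myeloid pair (smallest adjusted p 0.0554). Only 3 of all genes passed without the T pair, and 3 without the lineage-negative pair.

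Markers of cell lineages also fell as lists by camera. The normal libraries held RNA of other cells, with Pax5 at 149.5 in normal T and 164 in lineage-negative cells. Prss34 had 84.5, 293.7, 99.4 and 1436 in normal B, T, myeloid and lineage-negative cells, and Gata2 followed the same order. Falls in markers of other cell types can therefore reflect such cells in the normal libraries, which was not tested. The same applies in part to the mature B and monocyte lists above. Pan-B genes had a median of -3.60 (2 of 13 fell, 12 adjusted over the list alone, camera adjusted p = 2.85e-07), pro-B and pre-B genes -2.95 (4 of 12 fell, such as Rag1 with -3.60 ± 0.67 SE; 8 adjusted over the list alone; 0.000106) and NK cell genes -2.61 (3 of 8 fell, 8 adjusted over the list alone; 5.54e-05). Mast cell and basophil genes had -3.86 (2 of 6 fell, 6 adjusted over the list alone; 0.000201), plasmacytoid dendritic cell genes -2.55 (3 of 8 fell, 6 adjusted over the list alone; 0.000533) and megakaryocyte genes -2.06 (1 of 7 fell, 4 adjusted over the list alone; 0.00266). Adhesion genes had -1.68 (2 of 12 fell, 5 adjusted over the list alone; 0.00230), thymocyte genes -1.73 (2 of 14 fell, 5 adjusted over the list alone; 0.00460) and plasma cell genes -1.18 (1 of 7 fell, 3 adjusted over the list alone; 0.0305). For these 9 lists the adjusted p = 0.332 with an estimated correlation. Stem and progenitor genes had -1.59, where Gata2 fell (-4.31 ± 0.82) and 8 fell adjusted over the list alone (camera adjusted p = 0.00158, and 0.382 with an estimated correlation). AML did not share this fall: its stem and progenitor median was 0.28, within the range of random lists. Of 15 measured genes, 5 were at least 2-fold higher and 5 lower in AML. Neutrophil genes had -1.88 with none passing over all genes or adjusted over the list alone (limma; camera adjusted p = 0.00580; adjusted p = 0.614 with an estimated correlation), and their medians in B-ALL (1.77) and T-ALL (0.22, or -0.01 under median-ratio scaling) did not share this direction under the deposited scaling. That call ended without the myeloid pair (adjusted p = 0.668) and without the lineage-negative pair (0.0516), and the plasma cell call ended without the lineage-negative pair (0.0751). No single gene passed limma without the myeloid pair (smallest adjusted p 0.0554), and only 3 of all genes passed without the T pair or without the lineage-negative pair.

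The other 9 lists did not pass camera. These were effector T (adjusted p = 0.0672), promyelocyte granule (0.497), erythroid (0.0527), stroma (0.920), p53 target (0.951), BCL2 family (0.0735), tumour suppressor (0.130), Polycomb and DNA methylation (0.0602) and MYC network genes (0.627). For the MYC network the median (-0.36) and the mean (0.03) differed in sign, as they did for stroma (0.03 and -0.10). By camera 7 lists were higher and 16 lower of 32, and by camera with an estimated correlation or by fry none passed (smallest adjusted p 0.332 and 0.0553). Genes of the single comparisons overlapped as well. Of 8368 genes measurable in all comparisons, 282 were at least 2-fold higher in all 4, where independent calls give 16.6, and 425 were lower in all 4, where they give 18.9.

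**Figure D3:**
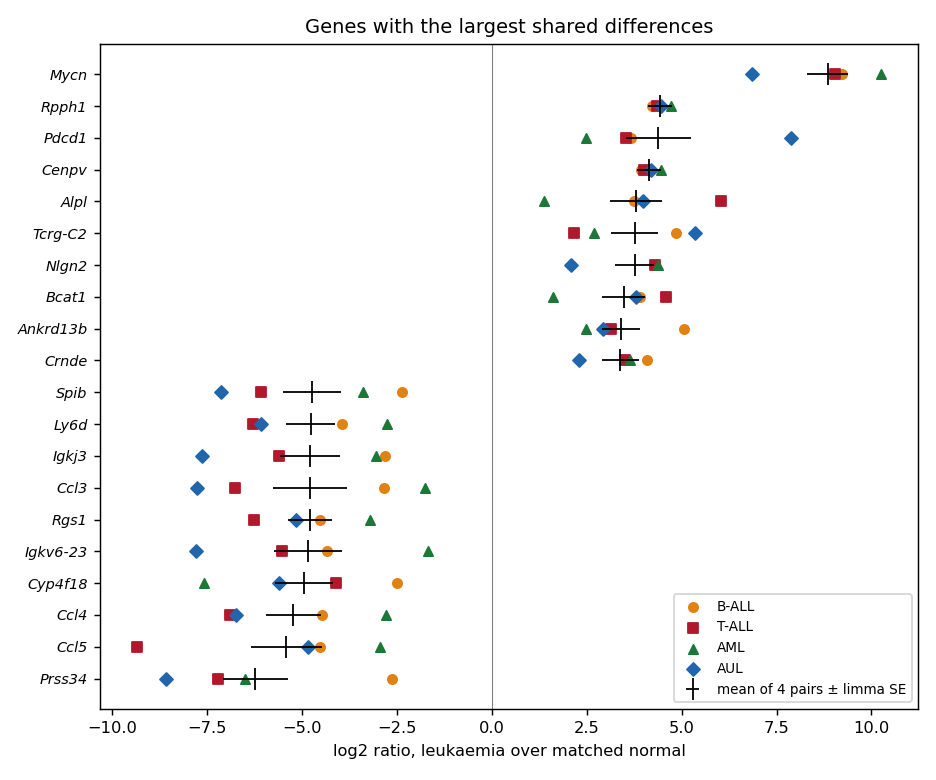
Log2 difference (leukaemia minus normal) of the 10 genes with the highest and the 10 with the lowest mean among those passing limma, with 1 point for each of the 4 pairs and a bar for the mean ± SE from limma (n = 4 pairs). Mycn has the highest mean (8.84) and Prss34 the lowest (-6.22).

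Lineage identity was compared by asking whether each leukaemia differs from the other leukaemias in the genes by which a normal population differs from the other normal populations. In these differences B-ALL resembled normal B cells most (Pearson correlation 0.37 across genes), T-ALL normal T cells (0.41) and AML normal myeloid cells (0.36). AML had 0.28 with lineage-negative cells. AUL resembled normal T cells most (0.42) and had -0.23 with its lineage-negative counterpart. Among the leukaemia libraries the expression of T-ALL and AUL was closest (0.92). Whole libraries gave another order for B-ALL and AML. B-ALL correlated with lineage-negative cells at 0.864 and with normal B cells at 0.846. AML correlated with lineage-negative cells at 0.803 and with normal myeloid cells at 0.697. T-ALL (0.804) and AUL (0.824) were closest to normal T cells among the normal libraries. The genes that set each leukaemia apart from the others matched these lineages in part. B-ALL had Pax5 (482.1, log2 difference 7.87 over the next leukaemia), the receptor chain Cd79a (590.3), Vpreb3 (256.3) and Reln (131.1). T-ALL had the inhibitory receptor Klra1 (108.2, 6.68), the innate-like T-cell factor Zbtb16 (98.4), Mpp4, and the cytokine receptors Il17rb (135.7) and Il9r (51.4). AML had Dmrt1 (6.44), the enkephalin gene Penk (88.6), the adhesion receptor Vcam1 (299.9), Cyp26a1 and Thbs4. AUL had the liver genes Alb (80.03, 6.27) and Afp (52.9), the small nuclear RNA Rn7sk (187.4, 5.01), Gsta4 (72.4) and the IgG receptor Fcgrt (32.9). Alb also had 31.2 to 34.6 in the 4 normal libraries, and at most 0.0526 in the other 3 leukaemias.

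**Figure D4:**
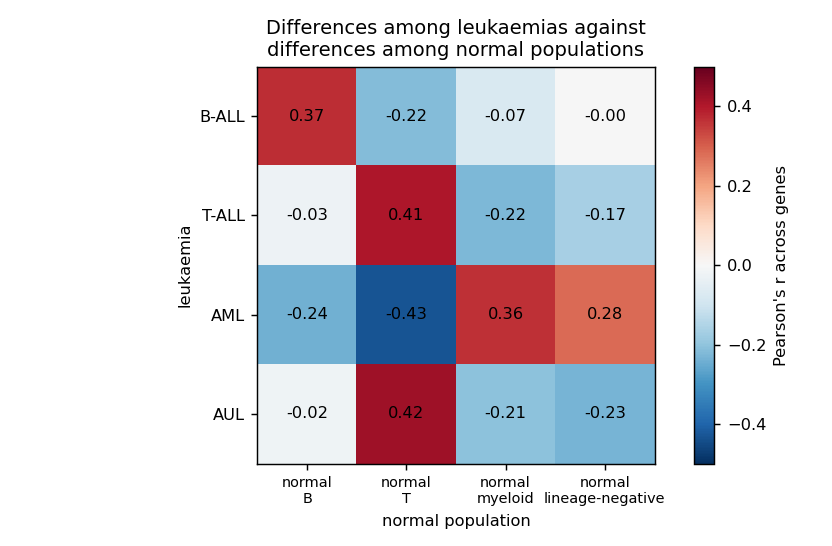
Pearson correlation across genes between the lineage differences of each leukaemia and those of each normal population. B-ALL, T-ALL and AML are highest with their own counterparts (0.37, 0.41 and 0.36), and AUL is highest with normal T cells (0.42).

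Fewer receptor segments passed an FPKM of 10 in T-ALL and B-ALL than in their normal counterparts. Of 22 listed T-cell receptor beta variable segments, 17 had an FPKM of at least 10 in normal T cells, 1 in T-ALL (Trbv12-1, 473.4), 2 in B-ALL and 0 in AUL. T-ALL also had the delta segment Trdv1 (272.2) and the gamma segment Trgv2 (208.7), while the delta constant gene Trdc was not detected in it. AUL transcribed the constant segments Trbc2 (423) and Trac (98.6). A single alpha segment of 70 passed 10, Trav21-dv12 (453.3), which is named for both alpha and delta. AUL also had Trdc at 65.2, against 20.7 in normal T cells, with the delta segment Trdv5 at 16.6. Its gamma transcripts included Tcrg-C4 (134.1) and Trgv2 (46.1). Of 123 immunoglobulin heavy variable segments, 78 passed 10 in normal B cells and 8 in B-ALL, and of 111 kappa segments 73 and 11. These counts move with the summed level, which was 316.5 in B-ALL against 3271 in normal B cells for heavy and 385 against 4097 for kappa segments. The top kappa segment took 5.81% of the sum in B-ALL and 4.53% in normal B cells, and the top heavy segment 16.2% and 5.68%. The heavy constant genes Ighm (704 against 2952) and Ighd (38.4 against 561) and the kappa constant gene Igkc (499 against 2263) were lower in B-ALL than in normal B cells. Normal lineage-negative cells had 64 heavy variable segments at 10 or more.

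**Figure D5:**
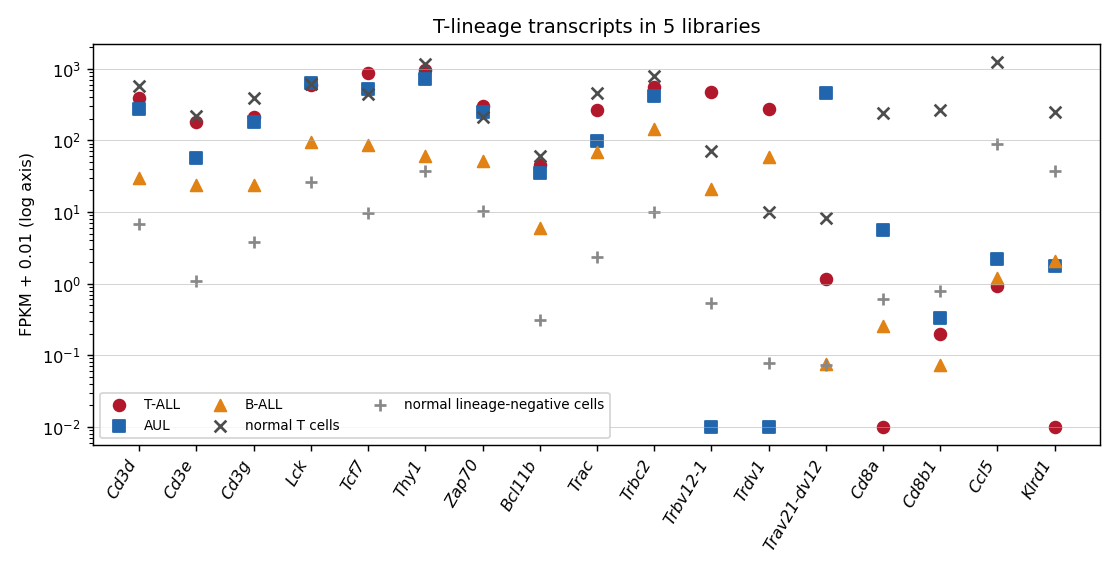
FPKM plus 0.01 (log axis) of T-lineage genes and receptor segments in T-ALL, AUL, B-ALL, normal T cells and normal lineage-negative cells, 1 point per library. AUL has CD3 chain and Lck transcripts well above lineage-negative cells (Lck 626 against 26.03) but little Cd8a (5.55 against 237.7 in normal T cells).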

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

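The rule that picked the 2 list results was fixed before the data were examined, whereas all tests of explanations here were chosen after the results were seen. The promyelocyte granule list moved in opposite directions, with a median log2 ratio of 2.24 in AML and -5.22 in AUL, a difference of 7.46, and it was lower in T-ALL too (-1.12). The neutrophil maturation list also moved in opposite directions, with 1.77 in B-ALL and -6.09 in AML, a difference of 7.86, and it was lower in AUL as well (-3.11), whose normal counterpart held neutrophil transcripts such as Ltf at 2785 and Ngp at 2436. With 1 library per group neither difference was tested.

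The AUL library, sorted as CD3-negative, held T-cell transcripts at a median of 53.3% of normal T cells over the pan-T list. Admixed normal T cells, which the gate would remove, are argued against by 24 of 71 abundant normal T-cell transcripts (33.8%; FPKM of at least 50 and at least 8-fold above the other normal libraries) that stood under 0.1 times the pan-T ratio, with Ccl5 at 0.179% and Cd8b1 at 0.119% of normal T cells. Admixed T-ALL cells are argued against by 18 of 67 abundant T-ALL transcripts (26.87%), with Mpp4 at 0.127% and Il17rb at 0.280% of T-ALL, and with Klra1, Trbv12-1 and Trdv1 not detected. T-lineage cells without a rearranged beta variable segment stay open as a hypothesis: the listed Trbv segments summed to 0.119% of Trbc2, against 138% in normal T cells and 86.2% in T-ALL. This could mean that AUL cells transcribe T-lineage genes without a complete surface receptor, although a segment not analysed here would be missed. T cells of another kind, low in Ccl5 and Cd8b1, were not excluded, and the alpha segment Trav21-dv12 was present at 453.3. Delta and gamma transcripts were present too (Trdc 65.2, Trdv5 16.6, Tcrg-C4 134.1, Trgv2 46.1), so a receptor of gamma and delta chains was not excluded.

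The B-ALL library, sorted as B220-positive, held neutrophil and T-cell transcripts above normal B cells. Admixed mature neutrophils are a candidate source of the first, since 21 neutrophil genes stood at a similar ratio to normal myeloid cells (median 6.02%, 3.57% to 9.52%; S100a8 7.89%, S100a9 5.75%, Ngp 6.08%), with an SD of the log2 ratio of 0.393 against 3.27 in AML; the B220 gate would remove such cells. For the T-cell transcripts, normal T cells are argued against by 17 of 71 abundant transcripts (23.94%) under 0.1 times the pan-T ratio of 9.56%. Cells of the T-ALL are argued against as the whole source by 8 of 68 abundant transcripts (11.76%) under 0.1 times the pan-T ratio of 9.63%, although Trdv1 (58.9) and Trbv12-1 (21.0) were present beside Trbv2 (41.3). Another T-lineage clone, or T-lineage genes in the leukaemia cells themselves, were not tested and stay open.

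Liver transcripts stood in the 4 normal libraries and in AUL but were near 0 in the other 3 leukaemias: Alb had 33.5, 31.2, 34.6 and 34.02 in normal B, T, myeloid and lineage-negative cells, 80.03 in AUL and at most 0.0526 elsewhere, and 29 to 31 of 32 liver genes reached an FPKM of 0.1 in normal libraries, 27 in AUL and 2 to 3 elsewhere. Traces of liver RNA from a shared preparation or run of the normal libraries could explain the first part, as the lowest Spearman correlation over 32 liver genes between 2 normal libraries was 0.707 (across genes) and Alb varied 1.11-fold, as little as 0.215% of 3249 genes of similar level. The same liver RNA in AUL is argued against by a highest correlation of 0.453 with a normal library, and AUL had Afp at 52.9 but Cyp2e1 at 0.118. No biological explanation was tested. If the normal libraries shared a preparation, it coincides with the normal state, so a part of any difference shared by the leukaemias cannot be told apart from it, including Rpph1 (198, 207, 226 and 208 in the leukaemias against 9.59, 9.24, 7.56 and 8.53).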

How the results depend on the processing

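The voom alternatives and the counts without genes of other normal populations were chosen after seeing the data. All other alternatives were planned. The Mycn level kept its direction (log2 difference 8.602 to 9.17 under the scalings), and the lineage correlations stayed within 0.05 of their values in 24 comparisons with settings. Of 610 alternative list medians in single comparisons, 587 kept their call or their lack of one, 17 gained a call and 6 lost theirs. None went from a call on 1 side to a call on the other. The random lists were redrawn under each setting, so a change of scaling moves them together with the list. A median within their range could change sign and still count as kept, as the mitotic list in AML did under median-ratio scaling. With a pseudocount of 5, the genes at least 2-fold higher and lower numbered 1061 and 1289 in B-ALL, 1406 and 1455 in T-ALL, 775 and 1818 in AUL, and 1664 were lower in AML, while 167 and 196 were shared by all 4 comparisons. The 4-fold rule gave 361 and 743 in B-ALL, 557 and 1099 in T-ALL, 1874 and 1238 in AML, 357 and 1452 in AUL, and 15 and 79 shared by all 4. A larger pseudocount and a stricter rule lower these counts by construction, and leaving out the FPKM minimum could not change them because the 2-fold rule itself needs an FPKM of 1. Median-ratio scaling gave 2477 higher and 4410 lower in AML. Across lineages limma called 140 genes higher and 268 lower. Those of the 408 that a setting still tested kept their direction in it (some settings drop genes). Each of the 408 had the same direction in 4 of 4 pairs. Another pseudocount, filter, trend or block, or a pair left out, therefore could not reverse them, and only another scaling or quantile normalization could. The counts were 309 and 530 with a pseudocount of 0.1, 3 and 0 with a pseudocount of 5 (3683 at an unadjusted p under 0.05), 250 and 637 with median-ratio scaling, 71 higher with scaling to a common FPKM sum, 3 and 0 without a filter (4366 at an unadjusted p under 0.05), 434 and 507 with an FPKM minimum of 5, 659 and 506 with quantile normalization, 72 higher without a trend, and 256 and 536 with voom. Without the replicate block, that is without pairing by gate, limma called 8 higher and 33 lower. With 1 pair left out the counts ran from 0 to 11 higher and 0 to 158 lower: 11 and 158 without the B pair, 2 and 1 without the T pair, 0 and 0 without the myeloid pair (3566 at an unadjusted p under 0.05), and 2 and 1 without the lineage-negative pair. Leaving out a pair removes residual degrees of freedom; for the other changes the cause was not tested. Of the named genes' 297 values across lineages, 190 kept their call, 107 lost it and none reversed. For the same reason, a reversal was possible only under another scaling or quantile normalization. Camera called 7 to 8 lists higher and 13 to 18 lower in the other settings, but 0 and 0 with an estimated correlation and 0 and 0 by fry. With an FPKM minimum of 5 the stem and progenitor and plasma cell lists lost their calls (both adjusted p 0.0626), and the plasma cell list also did without the block (0.0723). Members at 0 fragments lie in 25 list medians, and at their bound 13 of these moved by over 0.1, by at most 2.29 (mast cell and basophil genes in T-ALL, -4.70 to -6.99). Neither edgeR nor DESeq2 was run. The deposited values are FPKM, and the recovered fragments were used only for depth, counting intervals, bounds and the added voom alternative. Depth limits values near an FPKM of 1, which rest on 52.8 fragments for a gene of median length in AUL.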

Other observations

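The tests of splits were chosen after the counts were seen, whereas the gene lists were planned. Some cell death genes fell across the lineages. Among BCL2 family genes, the anti-apoptotic Bcl2 fell (-2.92 ± 0.61 SE, limma adjusted p = 0.0497, lower in 4 of 4 pairs), from 16.5 to 3.15 FPKM in B-ALL, from 88.4 to 2.505 in T-ALL and from 16.3 to 0.554 in AUL. Bcl2l1, which encodes the anti-apoptotic BCL-XL, fell too (-1.98 ± 0.40, adjusted p = 0.0446), as did the pro-apoptotic Bmf (-3.04 ± 0.42, adjusted p = 0.0326). These 3 genes fell over all genes, and 4 fell and 1 rose adjusted over the list alone, while the list as a whole did not pass camera. As for all genes, these calls ended without the myeloid pair (limma, smallest adjusted p 0.0554). The T and lineage-negative pairs mattered too, with 3 genes called over all genes when 1 of these pairs was left out. The pro-apoptotic Bax had 154, 224, 112 and 202 in the leukaemias against 80.1, 130.2, 30.5 and 91.1 in the normal cells, without passing over all genes (1.18 ± 0.34 SE, limma adjusted p = 0.0715, higher in 4 of 4 pairs), and it was the gene that rose adjusted over the list alone. Among tumour suppressors and cell cycle inhibitors, Cdkn1b fell (-2.35 ± 0.37, adjusted p = 0.0360) and so did Cdkn2d (-2.18 ± 0.47, adjusted p = 0.0497). Cdkn2a had 219.9 in B-ALL, 12.98 in T-ALL, 0.703 in AML and 12.1 in AUL, against 0.430, 0.835, 0 and 0.463 in the normal cells. Trp53 itself had 93.0, 103.5, 68.1 and 112 in the leukaemias against 74.0, 75.4, 18.2 and 91.1. The p53 targets went both ways: Perp had 45.5 in AML against 1.87, while the death receptor gene Fas had 0.301 against 40.9.

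Neither the chromatin list nor the erythroid list passed camera, and no difference between leukaemias was tested. The DNA methyltransferase gene Dnmt1 had log2 ratios of 1.57 in B-ALL, 1.76 in T-ALL and 1.90 in AML, and 235.6 against 145.0 FPKM in AUL. The Polycomb gene Cbx2 had 1.70 in B-ALL, 1.55 in T-ALL and 1.22 in AUL, with 0.228 against 0.469 FPKM in AML, whereas Cbx7 had -1.69 in B-ALL and -1.50 in T-ALL but 1.38 in AUL and 18.3 against 10.3 FPKM in AML. In AUL the erythroid factor Gata1 (0.266 against 22.4) and carbonic anhydrase Car1 (0.453 against 91.5) were low, whereas the beta globin gene Hbb-bs was higher (86.1 against 12.5). AUL also had ribosomal RNA gene Rn18s-rs5 at 1293, against 86.4 to 275 in the other libraries.

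Other splits of the libraries were tried for the gene counts. Without the block, limma called 41 genes for the real split, and 2 of the 35 splits into 4 and 4 gave as many, so chance cannot be excluded. The highest other split gave 98 genes, setting B-ALL and the normal B, T and lineage-negative libraries against T-ALL, AML, AUL and normal myeloid cells. With the block, the real split gave 408 genes and the highest of the others that part all 4 pairs gave 0. It was the 1 split of 8 to reach its own count, and 8 splits are too few for a share under 0.05. Among the 32 splits of 35 that could be fitted with the block, the highest other gave 8.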
